A study of Mus musculus with 6 samples.

How the data were processed

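Total RNA of naive CD4 T cells was sequenced in 6 mouse libraries. Per the labels' protocols, the cells were sorted by flow cytometry from spleen and lymph nodes, the RNA was purified with Trizol, and ribosomal RNA was depleted before library preparation with a KAPA RNA HyperPrep kit. The genotype label put 3 libraries in the control group, mice whose Slc23a2 alleles are flanked by loxP sites (WT), and 3 in the knockout group, mice that also carry the Cd4Cre transgene (KO). The labels do not say whether the libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical.

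The deposited table holds expected counts per gene. Per the submitters' processing notes, STAR and RSEM were used with the mouse build mm10, and no versions were given. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of a gene and of a gene overlapping it on the other strand were treated as possibly mixed. The table has 55665 rows, of which 92 are spike-in controls with a count of 0 in each library and 55573 are genes. Among rows with any count, 15.3% of the values were not whole, and values were rounded to whole numbers before testing. Positions were taken from the GENCODE annotation of the same build, in which 55180 of the gene identifiers matched with their version and 55480 without it.

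Total expected counts ranged from 23672697 to 29743966 per library, so 3 counts correspond to 0.101 to 0.127 CPM. CPM values (counts scaled to a common library size) were computed here from the deposited expected counts with TMM library sizes. Genes were kept by filterByExpr with its minimum count of 10, which left 14976. KO was compared with WT by edgeR 4.0.16 (R 4.3.3), with a quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05, and without a block for the replicate number. Log2 fold changes are KO minus WT, and the standard error is the absolute log2 fold change divided by the square root of F. Errors after ± are SDs over 3 libraries. Single values such as a class's share of counts were compared by an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

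Before the data were examined, 31 gene lists, the tests, the rule for naming genes and most alternatives were fixed. The 30 lists with at least 5 tested members were tested by camera with a preset correlation of 0.01 (limma 3.58.1), with adjustment over the lists. The genes named are Slc23a2, the 12 largest rises and 12 largest falls among changed genes with a mean of at least 2 CPM and no overlap between groups, up to 4 changed members of each list (or the member with the smallest p), and 18 fixed genes. Unnamed gene models, receptor and immunoglobulin variable, diversity and joining segments, Xist and genes of chromosome Y were passed over in the ranking. Some genes that the rule takes are not reported here. Genes outside this rule are marked where they appear.

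The test was checked on 10 simulated data sets of 14976 genes, drawn from the libraries' own means, depths and dispersions, with 200 genes changed in each. For KO against WT, 92.7% of the genes simulated with a log2 change of 2 were recovered, 73.7% of those with a change of 1 and 30.9% of those with a change of 0.5. On average 8.18% of the simulated calls were false, above the nominal 5%. A list of 25 genes raised by 0.5 was called in 10 of 10 simulations, and 1 of 190 unchanged lists was called. These lists were random genes drawn independently, so the rate does not cover lists whose members vary together. The estimated correlation between members was 0.41 in the type I interferon list and 0.90 in the ribosomal protein list.

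The alternatives were other scaling (RLE, or the total count alone), no filter on low counts, a stricter filter of 5 CPM in 3 libraries, the replicate number as a block, each library left out, DESeq2 1.42.0, limma-voom, stricter thresholds, the changed genes without markers of other cell types, and for lists an estimated correlation, fry, and lists without shared members. Alternatives added after seeing the data were protein-coding genes alone and the newer quasi-likelihood method of edgeR. The latter was added because the fit without a filter gave infinite prior degrees of freedom, against 6.56 with the filter, so that each gene's own spread between libraries no longer entered its test.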

Results

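Gene expression was measured by RNA sequencing in naive CD4 T cells from spleen and lymph nodes of mice with loxP-flanked Slc23a2 alleles, without (WT, n = 3) or with (KO, n = 3) the Cd4Cre transgene, which deletes the flanked part in T cells. Slc23a2 encodes a sodium-dependent transporter of ascorbate (vitamin C). The comparison asks how the transcriptome of naive T cells differs when this gene is targeted in T cells. No group carried Cd4Cre without the loxP-flanked alleles, so the deletion and the transgene itself cannot be told apart. The WT libraries held 29743966, 28764379 and 27327818 expected counts and the KO libraries 23672697, 26017876 and 26061099. Between 20131 and 21593 genes had at least 1 count. The libraries were separate, as each pair differed by more than sampling noise (chi-square per degree of freedom from 8.86 to 52.3). Xist was high and genes of chromosome Y had 0 to 4 counts in each library.

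Slc23a2 (ENSMUSG00000027340.15, chromosome 2 from 132052496 to 132145108, minus strand, mm10) was lower in each KO library than in each WT library. It had 58.1 ± 4.29 CPM in WT and 31.8 ± 0.38 CPM in KO, a log2 fold change of -0.87 (SE 0.08, edgeR adjusted p = 0.000317), which left 54.8% of the WT level. The exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. The count is over the whole gene, so transcript from exons outside the deleted part and transcript of undeleted alleles are not told apart by it.

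The KO libraries had higher Eomes, a T-box transcription factor of effector and memory T cells, and lower Cd5 and Cd6, surface receptors that restrain T cell receptor signalling. Eomes rose from 5.06 ± 0.37 to 32.0 ± 2.79 CPM (log2 fold change 2.66, SE 0.11, edgeR adjusted p = 1.2e-06). Cd5 fell from 338 ± 10.5 to 202 ± 13.8 CPM (log2 fold change -0.74, adjusted p = 0.000731) and Cd6 from 376 ± 12.8 to 217 ± 16.2 CPM (log2 fold change -0.79, adjusted p = 0.000561). Both lie close together on chromosome 19 (10717116 to 10739002 and 10789341 to 10830058), so their falls may not be separate observations. Tet1, which encodes an ascorbate-responsive 5-methylcytosine dioxygenase, fell from 86.3 ± 2.84 to 34.3 ± 5.97 CPM (log2 fold change -1.33, adjusted p = 0.000127).

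Of 14976 genes tested, 703 changed, 286 of them higher and 417 lower in KO. Among protein-coding genes, 241 were higher and 296 lower. The change reached 1 on the log2 scale in 130 higher and 183 lower genes. The groups did not overlap for 701 of the changed genes and for 22.6% of the genes tested, where chance gives 10%. The count of changed genes was 400 without WT replicate 2, 390 without KO replicate 1, 359 without KO replicate 2 and 372 without KO replicate 3.

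**Figure D1:**
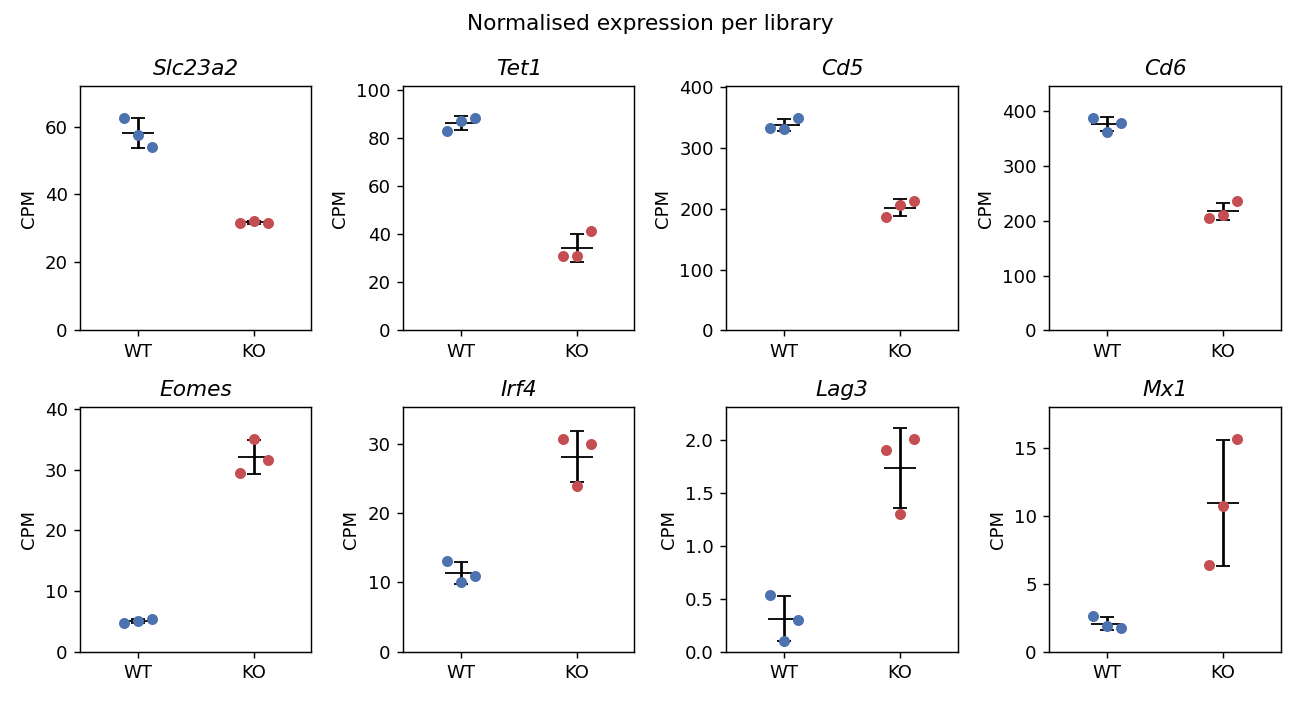
Normalised expression (CPM, vertical axes from 0) of 8 genes in each of 3 WT and 3 KO libraries; points are libraries, horizontal bars are means and error bars are SDs. Slc23a2, Tet1, Cd5 and Cd6 lie lower in KO, with Tet1 at 34.3 against 86.3 CPM, and Eomes, Irf4, Lag3 and Mx1 lie higher, with Eomes at 32.0 against 5.06 CPM.

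Among the 12 largest rises, Fam84b was the most abundant, at 33.4 ± 1.28 CPM in WT and 250 ± 21.0 CPM in KO (log2 fold change 2.90, adjusted p = 1.38e-07). Ms4a4c rose by 2.64, Map2 by 3.05, Luzp1 by 2.08, Setbp1 by 2.13, and Il18rap, a subunit of the interleukin 18 receptor, by 2.25 on the log2 scale. Trim30c (4.84) and Ms4a4c belong to families of similar genes among which reads can be split, so their values are uncertain. Transcripts of other cell types were also among the rises. Mpo, the myeloperoxidase of neutrophils and their precursors, rose from 0.65 ± 0.28 to 5.03 ± 2.56 CPM, and the immunoglobulin constant genes Igha (log2 fold change 2.89, from 10.9 ± 9.13 CPM) and Ighg1 (0.64 ± 0.41 to 5.59 ± 1.77 CPM) rose with it. Without WT replicate 3, the log2 fold change of Igha was 3.83. Fam84b, Map2, Eomes, Ms4a4c and Mpo each overlap a gene on the other strand.

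Among the 12 largest falls, Gabrr2, a subunit of a GABA receptor, went from 10.8 ± 1.64 to 0.40 ± 0.14 CPM (log2 fold change -4.72, adjusted p = 3.4e-06). Igsf23 changed by -3.18, Prg4 by -3.48, Fbxo17 by -3.03, As3mt by -2.96, Sh3d19 by -2.24, Itga7 by -2.24, Vmn2r96 by -2.20, Grm6 by -2.13 and Lrrc75b by -2.07 on the log2 scale. Dapl1, a gene of naive T cells, fell from 37.6 ± 8.06 to 9.63 ± 1.67 CPM (log2 fold change -1.96, adjusted p = 0.00015). Prg4, Itga7 and Grm6 overlap a gene on the other strand.

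Interferon-induced genes were higher in KO. Of 32 tested members of the type I interferon list, 13 rose and 0 fell, with a median log2 fold change of 0.42. Adjusted over the list alone, 24 were higher and 1 lower. Mx1, an interferon-induced gene annotated here as a polymorphic pseudogene, rose by 2.40 (adjusted p = 0.00146) and Ifit3b by 1.75 (adjusted p = 0.00132). Of 20 members of the interferon gamma list, 6 rose and 0 fell (median 0.33), or 11 higher and 0 lower adjusted over the list alone, among them Iigp1 (1.13) and Gbp3 (0.80), both GTPases. Camera with the preset correlation gave adjusted p = 1.27e-20 for the type I list and 1.24e-08 for the interferon gamma list. With an estimated correlation, the unadjusted camera p was 0.0400 and 0.108. For both, adjusted p was then 0.512, a value that the adjustment ties across lists. The list of macrophages, monocytes and dendritic cells was called higher beside them, with a median log2 fold change of 0.80 and 13 of 15 members above 0, and had adjusted p = 0.721 with an estimated correlation.

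Genes of effector and memory T cells were also higher on balance. Of 25 members, 5 rose and 1 fell (median 0.36), and 10 were higher and 2 lower adjusted over the list alone. The chemokine receptors Cxcr3 and Ccr2 rose by 2.24 and 1.40 on the log2 scale, though from 0.47 ± 0.31 and 1.40 ± 0.28 CPM, and Fasl fell by 0.82. Without WT replicate 3, the log2 fold change of Cxcr3 was 2.91. In the NK cell list, 1 of 6 members rose, Eomes, or 2 were higher and 1 lower adjusted over the list alone. In the list of gamma delta and innate-like T cells 1 of 5 rose, or 2 were higher and 0 lower adjusted over the list alone. The riser was Zbtb16, a transcription factor of innate-like T cells, with a log2 fold change of 2.16 from 0.29 ± 0.07 CPM. Camera adjusted p was 0.000146, 5.4e-06 and 0.00093 for these 3 lists, and for each adjusted p = 0.512 with an estimated correlation. The list of gamma delta and innate-like T cells was not called without WT replicate 1 (adjusted p = 0.087). Cd44 (-0.09, adjusted p = 0.822), a surface marker of memory cells, did not pass the test.

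Genes of the DNA methylation and TET list changed in both directions. Of 17 members, 1 rose and 2 fell, and the list was not called (adjusted p = 0.577, median 0.00, mean -0.09). Uhrf1 rose by 0.88 and Gadd45a fell by 0.92, beside Tet1. Tet2 had a log2 fold change of 0.12 (adjusted p = 0.525) and Tet3 of 0.00 (adjusted p = 0.996). Of 19 histone demethylases, Kdm2b rose (0.44). In the ascorbate transport and recycling list, 1 of 11 members changed, Slc23a2 itself.

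Genes linked to T cell receptor signalling changed in both directions. Of 25 early genes induced through the receptor, 2 rose and 2 fell, or 4 were higher and 5 lower adjusted over the list alone. Among these, Irf4 (1.31) and Fosb (1.10) rose, and Fosl2 (-0.86) and Dusp5 (-0.64) fell. The list was not called (adjusted p = 0.974), and its test pointed up with a median of -0.01 and a mean of -0.02. Nr4a1 (-0.34, adjusted p = 0.387), Egr2 (0.31, adjusted p = 0.133) and Egr3 (0.28, adjusted p = 0.251) did not pass the test. Of 28 signalling components, Cd247, the zeta chain of the receptor complex, fell (-0.51). Of 13 self-reactivity markers, Cd5 and Cd6 fell and Nt5e, the ectonucleotidase CD73, rose (0.72), or 2 were higher and 3 lower adjusted over the list alone, with adjusted p = 0.0754 for the list. This list passed the threshold in the lower direction with no filter (adjusted p = 0.0268), with the stricter filter (0.0380), without WT replicate 1 (0.0349) and without members shared with other lists (0.000801), and its adjusted p was 0.512 with an estimated correlation. Among 26 anergy and negative regulator genes, 4 rose and 1 fell (5 higher and 2 lower adjusted over the list alone), including Lag3 (2.45, from 0.31 ± 0.21 CPM), Cd160 (1.09) and Tob1 (-0.66). Without WT replicate 1, the log2 fold change of Lag3 was 3.09. Of 23 genes of the naive state and quiescence, 2 rose, Ccr9 (1.09) and Nsg2 (0.39), and 3 fell, among them Dapl1 (-1.96) and Lef1 (-0.55). Izumo1r (-0.26), Il7r (0.22), Pdcd1 (0.20), Cd4 (-0.24), Foxp3 (-0.49), Ctla4 (-0.54) and Il2ra (0.64) did not pass the test. Fosl2 and Cd160 lost their call with DESeq2, and Cd160 whichever library was left out.

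**Figure D2:**
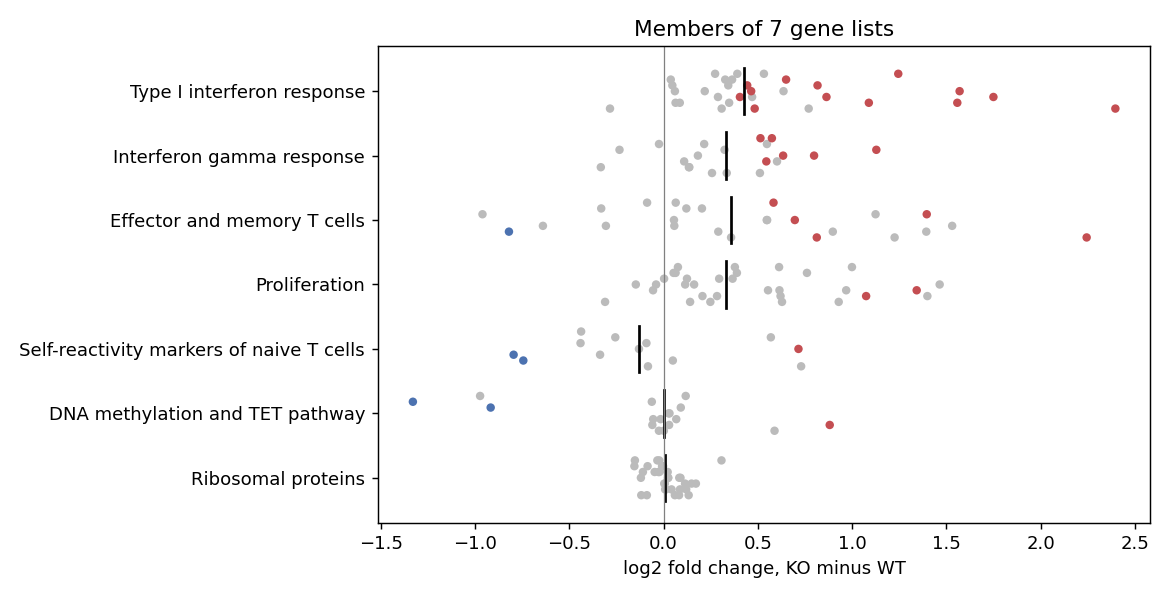
Log2 fold change (KO minus WT, horizontal axis) of each tested member of 7 gene lists (rows); red points are genes higher in KO, blue points lower, grey points not called, and black lines are list medians. The type I interferon list has its median at 0.42 and 13 genes called higher, and the ribosomal protein list has its median at 0.01 and 0 called.

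The other called lists had few changed members. Of 32 proliferation genes 2 rose, Tpx2 (1.34, from 0.91 ± 0.31 CPM) and E2f1 (1.07, from 1.39 ± 0.36 CPM), with a list median of 0.33 and adjusted p = 0.000116. Both genes lost their call without WT replicate 1 or 2 and without KO replicate 1, 2 or 3. The proliferation list was not called with the stricter filter (adjusted p = 0.0749) and had adjusted p = 0.512 with an estimated correlation. In the glycolysis list (22 members, median 0.17, adjusted p = 0.0386) and the list of mitochondrially encoded genes (15 members, median -0.30, adjusted p = 0.00795) 0 members were called. The smallest p belonged to Tpi1 (0.49, adjusted p = 0.0569) and mt-Atp8 (-0.86, adjusted p = 0.09). With an estimated correlation these lists had adjusted p = 0.512 and 0.613. The glycolysis list lost its call without WT replicates 1 (adjusted p = 0.0767) or 2 (0.101), without KO replicates 2 (0.0603) or 3 (0.0551), with the stricter filter (0.0530) and with protein-coding genes alone (0.0771), and the mitochondrial list without WT replicate 2 (0.0679). Lists of other cell types were called as well. Macrophage, monocyte and dendritic cell genes were called higher (adjusted p = 0.0102), with 0 of 15 members higher and 1 lower, Itgam (-0.81), or 2 higher and 1 lower adjusted over the list alone. Their call was lost without WT replicate 1 (adjusted p = 0.153) and without KO replicate 3 (0.0551). Neutrophil genes were called higher (adjusted p = 0.0333, 1 of 8, Mpo) and B cell genes lower (adjusted p = 0.0389, 1 of 17, Ighd, -1.57). With an estimated correlation they had adjusted p = 0.799 and 0.833. The neutrophil call was lost without WT replicate 1 (0.237), KO replicate 2 (0.102) or KO replicate 3 (0.0825) and with protein-coding genes alone (0.0519), and the B cell call without WT replicate 2 (0.336), WT replicate 3 (0.726) or KO replicate 2 (0.109) and with protein-coding genes alone (0.0672). With an estimated correlation, camera called 0 of the 30 lists (smallest adjusted p = 0.512). The 1 list at an unadjusted camera p under 0.05 was type I interferon. Fry's directional test called 0 lists, while its mixed test, which takes changes in either direction, called 22. Splits of the 6 libraries that mixed the genotypes, which keep part of the genotype difference, called 5 to 14 lists, against 11 in the real split.

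The 19 lists not called included CD8 T cells (8 members, adjusted p = 0.116), in which Cst7 (1.28) and Eomes rose and Cd8b1 (-1.48) and Klrd1 (-1.14) fell. Its median was -0.13 and its mean 0.10, and the test pointed up. The CD8 list was called with no filter (adjusted p = 0.0412) and with the stricter filter (0.0380). In the regulatory T cell list Gpr83 rose (0.73; 4 higher and 1 lower of 14 adjusted over the list alone), with a list median of -0.09, a mean of 0.12 and a test that pointed up. Cd40lg of the follicular helper list fell (-0.65), and Osgin1 (-1.29) and Txnip (-0.57) of the oxidative stress list fell. Of 21 p53 and apoptosis genes, Bcl2 (0.51) rose and Gadd45a (-0.92) and Fasl (-0.82) fell, or 6 were higher and 3 lower adjusted over the list alone. Ribosomal protein genes (33 members), nuclear-encoded respiratory chain genes (29), cholesterol biosynthesis genes (23) and HIF targets (18) had 0 called members. Their members with the smallest p were Rpl4 (0.31, adjusted p = 0.273), Ndufb8 (-0.18, adjusted p = 0.383), Fdps (0.35, adjusted p = 0.109) and Ddit4 (0.29, adjusted p = 0.127). Among erythroid and platelet genes 0 of 10 were called, with Hbb-bt at -0.93 (adjusted p = 0.391), and the list was called lower without WT replicate 1 (adjusted p = 3.27e-06). For the remaining lists not called, cholesterol biosynthesis passed without KO replicate 1 (adjusted p = 0.0245), heat shock and handling stress without WT replicate 3 (0.0373) or KO replicate 1 (0.0171), anergy and negative regulators without WT replicate 1 (0.0448) or KO replicate 2 (0.0499), and p53 and apoptosis without shared members (0.0422). Fosb was the 1 called of 21 heat shock and handling stress genes. The stroma and endothelium list had 3 tested members and was not tested as a list, and Fn1 rose in it (1.05). Cd8a had a log2 fold change of -1.14 (adjusted p = 0.289).

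Small structured RNAs took a smaller share of the counts in KO. The snRNA, snoRNA, scaRNA, misc_RNA, ribozyme and miRNA classes together made up 5.57% ± 0.61 of counts in WT and 3.92% ± 0.48 in KO, without overlap between the groups (exact permutation p = 0.1, the smallest possible). Most of this share was misc_RNA, at 4.61% ± 0.58 in WT and 3.29% ± 0.42 in KO, a class with 0 of 17 tested genes called. Of 157 tested genes of the classes, 26 fell and 0 rose, with a median log2 fold change of -0.93. The calls were 11 snRNA, 10 snoRNA, 2 scaRNA and 3 miRNA genes, classes of small share, so the share and the calls describe different genes. Several are near-identical copies with split counts, and the 26 hold 16 distinct profiles. Such copies also enter the median singly, and its value of -0.93 is that of Rnu1a1 and its copies. Medians of the single classes ran from -0.46 in misc_RNA to -1.12 in miRNA.

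**Figure D3:**
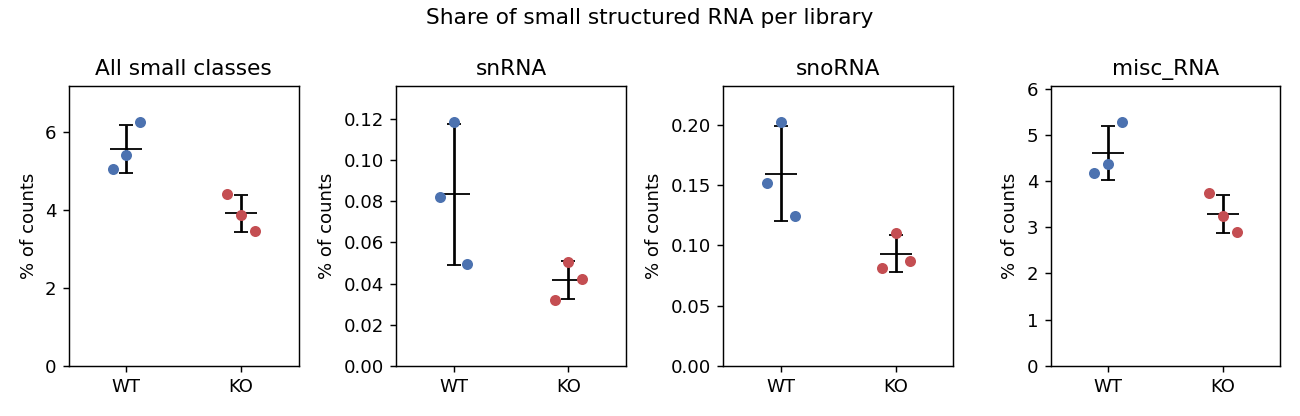
Share of expected counts (%, vertical axes from 0) of small structured RNA classes in 3 WT and 3 KO libraries; points are libraries, horizontal bars are means and error bars are SDs. The classes together lie at 5.57% in WT and 3.92% in KO, and the snRNA class overlaps between groups (0.0496% in the lowest WT library and 0.0506% in the highest KO library).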

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

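The 703 changed genes became 708 with RLE scaling, 707 with the total count alone, 502 with the stricter filter, 829 with DESeq2 and 683 with limma-voom, and between 38.4% and 44.9% of the calls were higher in KO in the settings run. Without the filter 1466 genes were called, a fit whose infinite prior degrees of freedom ignore each gene's own spread. With the newer quasi-likelihood method, added after seeing the data, 778 were called without the filter and 723 with it. The count was 270 at an adjusted p under 0.01, 313 with an absolute log2 fold change of at least 1, and 359 to 686 with a library left out, where fewer libraries enter each fit. Slc23a2 kept its direction and its call in each setting (log2 fold change -0.92 to -0.81 with a library left out). The 11 called lists became 7 with the stricter filter, 7 with protein-coding genes alone, 0 with an estimated correlation and 0 with fry, and 8 to 13 with a library left out. These were not always the same lists. With the stricter filter, 26 lists were tested and 5 of the 7 called were among the 11. Without WT replicate 1, 11 were called and 7 of them were among the 11. The type I interferon, interferon gamma, effector and NK cell lists stayed called under each scaling, filter, block and left-out library in which they had enough members. Ribosomal protein genes, not called with 6 libraries, were called lower without WT replicate 1 (adjusted p = 0.0101) and higher without WT replicate 3 (adjusted p = 0.00985), with adjusted p up to 0.969 without KO replicate 2, and the cause was not tested. Of 63 changed named genes, 22 lost their call in at least 1 setting, all 22 of them when a library was left out, and 0 changed sign. These were Bcl2, Ccr2, Cd160, Cd247, Cst7, Dusp5, E2f1, Fn1, Fosl2, Gbp3, Ighd, Itgam, Kdm2b, Klrd1, Lag3, Lef1, Nsg2, Osgin1, Tob1, Tpx2, Txnip and Uhrf1. Whether equal replicate numbers pair the libraries is not settled. Deviations of same-numbered libraries correlated at -0.03, 0.23 and 0.06, and those of differently numbered libraries at -0.24 to 0.15. With a replicate block 780 genes and 10 lists were called, without the B cell list (adjusted p = 0.0652), and Slc23a2 had a log2 fold change of -0.87. Of simulated log2 changes of 0.5, 30.9% were recovered, and how far depth sets this was not tested. Levels under 0.101 to 0.127 CPM correspond to fewer than 3 counts.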

Other observations

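The tests of cell types in the sort and of neighbouring genes were chosen after the results were seen. Scarna10, Rnu12 and Rnu3a and the genes of the tests of cell types lie outside the naming rule and were chosen after their values were seen, whereas the nuclear long RNAs were chosen before. Further small RNA genes lower in KO included Scarna10 (557 to 336 CPM, log2 fold change -0.73), Rnu12 (80.6 to 36.5 CPM, -1.14) and Rnu3a (88.6 to 52.4 CPM, -0.76). Summed markers of B cells (379 ± 78.6 and 335 ± 31.5 CPM in WT and KO) and of erythroid cells and platelets (805 ± 528 and 485 ± 165 CPM) varied widely between libraries, with exact permutation adjusted p = 0.5 for both. The groups did not overlap in the summed markers of NK cells (46.5 ± 4.09 and 66.7 ± 3.74 CPM) and of gamma delta and innate-like T cells (10.3 ± 1.44 and 15.0 ± 0.49 CPM), with exact permutation p = 0.1, the smallest possible, and adjusted p = 0.32. Without Eomes, the NK cell sum was 41.4 in WT and 34.7 CPM in KO.

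The real split of the 6 libraries called 703 genes, and the highest of the other 9 splits called 1. That made 1 of 10 splits with a count as large, and 10 splits are too few for a share under 0.05. For lists the real split called 11 and the highest other split 14, so 5 of 10 splits called as many. The type I interferon list was itself called in several mixed splits, with adjusted p down to 4.88e-11, although 0 of its members passed the gene test there, against 13 in the real split. Mixed splits keep part of the genotype difference, since their sides hold unequal numbers of each genotype, so their calls are not a rate of false calls. The genotype difference also lies within each side of a mixed split and widens the spread there. Few gene calls in mixed splits therefore decide nothing, for all genes or for the interferon members. The small p of the list test still says less than the members' own tests, because adjusted p was 0.512 with an estimated correlation.

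The higher interferon genes may reflect the genotype (the deletion or the Cd4Cre transgene itself) or an exposure of the mice that was not tested. Technical sources were weighed. The 13 called genes lie on 8 chromosomes, with at most 3 on one, which argues against an inherited segment acting through its own genes alone. A segment with a regulator of the others stays open, since the camera p at or below 7.41e-18 with any chromosome's members left out decides nothing. That planned test was void, because it removed at most 5 members. The same list test calls the list in mixed splits too, which keep only part of the genotype difference (adjusted p down to 4.88e-11). Macrophages, monocytes or dendritic cells in the sort, whose list had a median of 0.80, are argued against as the main source, as the myeloid list gained at most 82.0 CPM between any KO and any WT library and the 32 tested type I interferon genes, called or not, gained at least 299 CPM, but the profile of such cells was not measured and a small contribution is not excluded.

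Higher Eomes may likewise come from the naive cells or from effector, memory or NK cells in the sort, which was meant to exclude them. Ccl5, Nkg7, S100a4, S100a6 and Lgals1 were taken from textbook knowledge as abundant in such cells, whose profile was not measured here. Together they gained at most 5.23 CPM, and Eomes gained at least 24.01 CPM. Most of that sum is Lgals1 (13.3 and 8.52 CPM in WT and KO), and the other 4 had log2 fold changes of 0.55, 1.12, 1.23 and 0.90 without passing the gene test, together gaining at most 3.07 CPM. The comparison does not settle the source of Eomes, because the reference genes were chosen after their values were seen. The 25 tested members of the effector and memory list, fixed before, together went from 534 CPM in WT to 665 CPM in KO. For Cxcr3, Ccr2, Tbx21 and Zbtb16 the question stays open too, and the sources cannot be told apart. These genes together gained 3.92 to 7.23 CPM, a range that holds the same 5.23 CPM. Tbx21 itself did not pass the gene test (adjusted p = 0.0507).

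Lower small structured RNAs could be a product of RNA handling. Less nuclear RNA is argued against as the main source, as Malat1, Neat1, Xist and Kcnq1ot1 had a median log2 fold change of -0.014 against -0.93 for the small RNAs. These 4 ran from -0.23 (Malat1) to 0.21 (Kcnq1ot1). The lncRNA class had 22 genes higher and 46 lower (median -0.07), and the TEC class 4 higher and 40 lower (median -0.14). Protein-coding genes had a median of 0.01. A smaller loss of nuclear RNA is therefore not excluded. Poorer recovery of short RNA cannot be told apart from a change in the cells. Protein-coding genes under 600 bases differed from longer ones by -0.011 in median log2 fold change, and the planned reading of this value was too strong, because 0 coding genes were as short as the small RNAs' median of 144 bases.

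A further hypothesis was that changed genes sit in linked segments of background genome. Of 527 changed protein-coding genes whose identifier matched the annotation with its version (537 changed in all), 259 lay within 1 Mb of another changed gene of a different family, and 95% of 10000 random draws gave 253 to 305. Families were taken from the letters before the first digit of a symbol, so Cd5 and Cd6 did not count as neighbours of each other. The test does not settle the matter. In simulations of 11170 genes with 10% of the changed genes placed in 5 segments it detected 13% of cases, and 87.5% with 30% of them so placed.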
